A study of Arabidopsis thaliana with 12 samples.

How the data were processed

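The series holds 12 RNA-seq libraries from whole Arabidopsis thaliana seedlings: wild type and the geralt mutant at 5 and at 12 days of age, with 3 libraries in each of the 4 groups. Groups and library numbers were taken from the titles the submitters gave. Per the labels, seedlings grew in vitro on B5 medium with sucrose in 10 h of light and 14 h of dark and were harvested about 4 h after the lights came on. RNA was extracted from 100 mg of tissue, and polyadenylated RNA was made into libraries with the Lexogen mRNA-Seq kit. The libraries were sequenced as paired reads of 150 bases on a NovaSeq instrument, with 6 libraries on each of 2 lanes. The labels do not give the lane of a library, so lane was no term in any model. The design text speaks of 3 biological replications, without saying how plants were pooled or grown apart.

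Per the file headers, each library's table gives counts of reads per gene, split into total and unique gene reads, exon, intron and exon-exon reads. Reads were counted against TAIR10, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here, nor is whether a read pair counts as 1 or 2 or whether strand was used. The authors also deposited TPM values, which sum to 1000000 over the listed genes in each library. RPKM values in the same tables were scaled by the authors to a larger number of reads than the listed genes hold. The authors deposited 2 tables of their own comparisons of geralt with wild type, with log2 fold changes, p-values and FDR-adjusted p-values per the file headers. Those tables also give the higher of the 2 group means of RPKM, per the file headers. The test behind them is not given in the sources used here. All columns of per-sample values in the files belonged to the 12 libraries.

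The tables list 27655 genes, of which 27445 lie on the chromosomes, 88 in the plastid genome and 122 in the mitochondrial genome. Of the chromosome genes, 27444 had the start and end of the gene with the same locus code in the reference annotation used for symbols. Coordinates are those of the files. Total gene reads ran from 41.6 to 115.03 M per library, and 99.2% to 99.5% of them were unique gene reads. Genes with near-identical copies can share the rest, and genes that overlap or lie antisense to another cannot be told apart by these counts.

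Total gene reads were tested as deposited. Genes with too few reads for a test were left out with edgeR's filterByExpr by group, which kept 21122. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test was fitted to all 12 libraries with a mean per group and 8 residual degrees of freedom. Group means were contrasted for geralt against wild type at each age, for 12 against 5 days in each genotype, and for the interaction. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and 0.05 was the threshold. The standard error of a log2 fold change was its absolute value over the square root of its F statistic. Values per library are TMM-scaled counts per 1000000 reads (CPM), given as mean and SD over 3 libraries. For genes with few reads in a group, ratios of summed reads carry 95% counting intervals. These take reads as independent and cover counting error alone, not the spread between libraries.

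Altogether 27 gene lists were fixed before the data were examined, as were the designs and the alternatives not said to be added. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists, and again with a correlation estimated per list. Medians per library in the plot of plastid lists are of log2 CPM with a prior count of 2, minus each gene's mean over the 12 libraries. Camera on the age contrasts and the mean of both ages were added after the data were seen. Named genes followed a rule written beforehand. It took PHR2 and, per main comparison, the 6 largest rises and falls among genes past the threshold. These needed an average log2 CPM of at least 1 and no overlap between genotypes. The next 5 of each with a symbol followed, and up to 4 members with the smallest p of each list that passed or had a passing member. For the interaction and the age contrasts up to 3 members per list were taken. Measures of the libraries were compared by a two-sided exact permutation test that exchanged genotypes within ages.

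Libraries of a group were compared pairwise before use. Their counts differed by a chi-square of 68.0 to 511 per degree of freedom, so that no library was a copy of another. The tests were run on simulated counts drawn from the means, spreads and sizes of these libraries, with 200 changed genes among 21122. The changed genes all had an average log2 CPM over 1, genes were drawn independently of each other, and each contrast was simulated once. At 5 days edgeR recovered 73.1% of genes changed 4-fold and 17.9% of those changed 2-fold, over 20897 genes fitted. At 12 days it recovered 82.1% and 17.9% of them over 20884 genes. For the interaction it recovered 41.8% and 1.49% over 20918 genes. In wild type, 12 against 5 days, the shares were 76.1% and 26.9% over 20903 genes, and in geralt 85.1% and 10.4% over 20900. Unchanged genes made up 5.97% of edgeR's calls at 5 days and 21.7% of those by DESeq2. At 12 days the shares were 5.00% and 23.1%.

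Alternatives were RLE size factors, no low-count filter, a minimum of 1 CPM in 3 libraries, unique gene reads, organellar genes left out, a robust spread, fits to the 6 libraries of a comparison, DESeq2's Wald test, other thresholds, and leaving out each library. Leaving out wild-type libraries 4 and 12 together was added after the data were seen. The work used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.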

Results

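Polyadenylated RNA of whole Arabidopsis thaliana seedlings was sequenced in 12 libraries, 3 each of wild type at 5 days, geralt at 5 days, wild type at 12 days and geralt at 12 days. The mutant is a T-DNA line that the labels call both phr2 and geralt, and the series title names chloroplast formation and chlorophyll synthesis as its subject. Total reads in genes ran from 41.6 M in wild-type library 2 to 115.03 M in wild-type library 4, and 21122 genes had enough reads for a test. On the leading axis of a scaling plot, which held 32.2% of the variation, wild-type libraries at 12 days lay between -2.34 and -1.53 and geralt libraries at 5 days between 1.53 and 1.94. Wild-type library 4 lay at 0.39, apart from the other wild-type libraries at 5 days at -0.72 and -0.55. Geralt library 5 lay at 2.01, apart from the other geralt libraries at 12 days at -0.02 and -0.20. P-values of the gene test set a difference between groups against the spread between libraries of a group. Whether that spread is one between plants grown apart is not given.

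PHR2 (AT2G47590, chromosome 2, bases 19521774 to 19524095, plus strand), a member of the photolyase and blue-light receptor family, fell in geralt at both ages. At 5 days it measured 189 ± 92.4 CPM in wild type and 29.4 ± 9.64 CPM in geralt (SD, n = 3), a 6.43-fold lower level. At 12 days it measured 201 ± 7.51 CPM in wild type and 28.9 ± 3.93 CPM in geralt (SD, n = 3). The log2 fold changes were -2.68 (SE 0.37, edgeR adjusted p = 0.0128) at 5 days and -2.80 (SE 0.37, edgeR adjusted p = 0.0193) at 12 days. Each geralt library, at 20.6 to 39.7 CPM, lay below each wild-type library, at 89.2 to 271 CPM. The 12-day call ended without geralt library 5 (adjusted p = 0.0559) or 9 (0.0601), and the 5-day call without geralt library 1 (0.0542), 3 (0.121) or 7 (0.0980) or without wild-type library 2 (0.0602) or 8 (0.0542). A T-DNA line can keep reads outside the insertion, and counts per gene do not show where reads lie, so this check of the line is partial. The nearest tested genes on either side, U1A and MHX, had log2 fold changes of 0.13 (SE 0.23) and -0.05 (SE 0.18) at 5 days and did not pass.

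**Figure D1:**
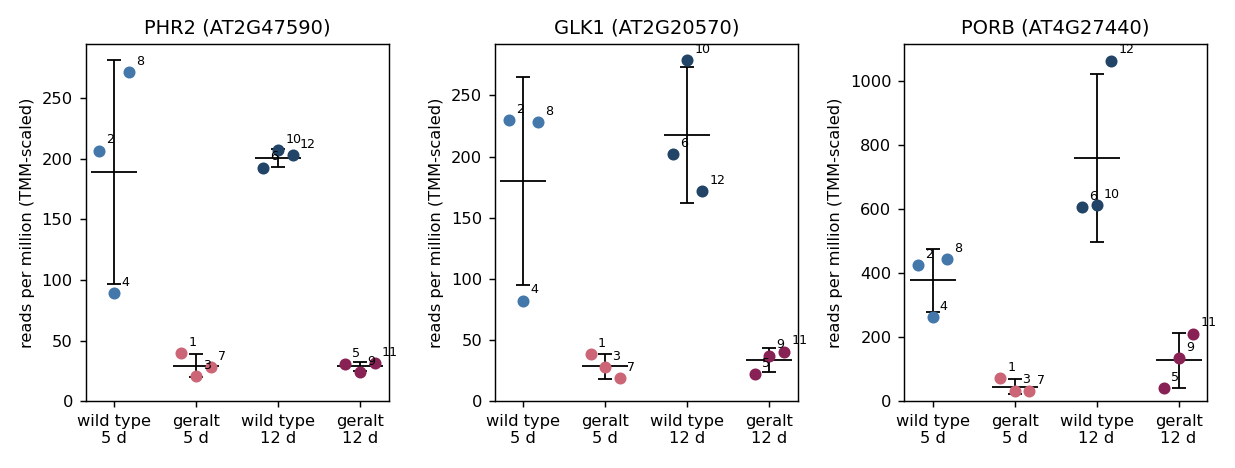
TMM-scaled CPM of PHR2, GLK1 and PORB in each library, by genotype and age in days; points are libraries with their numbers, and bars are the mean and SD of 3 libraries. For PHR2 the geralt libraries sit between 20.6 and 39.7 CPM, all below the wild-type libraries.

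At 5 days, the genes past the threshold in geralt included GLK1, PORB, PORC and RBCS2B, all lower, and STM, which was higher. GLK1, a transcription factor that drives chlorophyll and antenna genes, fell from 180 ± 84.7 to 28.6 ± 10.0 CPM (SD, n = 3; log2 fold change -2.65, SE 0.42). PORB and PORC, which reduce protochlorophyllide in light, fell by 3.04 (SE 0.55) and 2.28 (SE 0.37) on the log2 scale. RBCS2B, a small subunit of Rubisco, fell from 7049 ± 3975 to 67.7 ± 10.2 CPM (SD, n = 3; log2 fold change -6.70, SE 0.96); its near-identical neighbouring copies make its count uncertain. STM, a homeobox gene of the shoot meristem, rose from 7.20 ± 2.65 to 21.5 ± 3.85 CPM (SD, n = 3; log2 fold change 1.58, SE 0.25).

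Of the nuclear-encoded electron transport genes, 2 of 33 passed over all genes and 28 when adjusted over the list alone, all lower, with a median log2 fold change of -1.48 (camera FDR = 1.5e-25, adjusted p = 0.270 with an estimated correlation). PSBW of photosystem II fell by 2.04 (SE 0.34) and PSAH2 of photosystem I by 2.56 (SE 0.46). Light-harvesting antenna genes had a median of -1.91 (camera FDR = 3.59e-23, adjusted p = 0.270 with an estimated correlation), with 1 of 21 lower over all genes and 19 adjusted over the list alone. The passing member, LHCB4.3, fell by 2.60 (SE 0.39). Wild-type library 4 stood apart in both lists, with medians per library of -0.14 and -0.14 against 0.87 and 1.04 in library 2 and 0.82 and 1.05 in library 8, and the geralt libraries lay at -1.29 to -0.76 and at -1.53 to -0.83. Without library 4 the median log2 fold changes were -1.77 and -2.23. Plastid-encoded photosynthesis genes had a median of -1.95 with all 26 below 0 (camera FDR = 7.82e-20, adjusted p = 0.270 with an estimated correlation), 1 lower over all genes and 19 adjusted over the list alone. PSBH, a small photosystem II protein, fell by 5.33 (SE 0.85), and RBCL, the large subunit of Rubisco, had a log2 fold change of -6.43 (SE 1.2, adjusted p = 0.0504). Chlorophyll biosynthesis genes had a median of -0.78 (camera FDR = 1.35e-15, adjusted p = 0.270 with an estimated correlation), 2 of 34 lower over all genes and 18 adjusted over the list alone. The Calvin cycle list had a median of -0.96 (camera FDR = 6.44e-11, adjusted p = 0.276 with an estimated correlation), with 1 of 19 lower and 7 adjusted over the list alone.

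Carotenoid genes had a median of -0.43 (camera FDR = 3.09e-05, adjusted p = 0.276 with an estimated correlation), with 2 of 15 lower and 4 adjusted over the list alone. PSY, phytoene synthase, fell by 1.85 (SE 0.28), and BCH2, a carotene hydroxylase, fell by 1.85 (SE 0.32). Lists also called lower, without a member past the threshold over all genes, were plastid ribosomal proteins (median -0.32, 5 of 22 adjusted over the list alone), plastid protein import, insertion and proteolysis (median -0.46, 1 of 18), phosphate starvation (median -0.36, 4 of 17) and iron homeostasis (median -0.57, 5 of 18). For ribosomal proteins and import the adjusted p = 0.388 with an estimated correlation, for phosphate the adjusted p = 0.276 with an estimated correlation and for iron the adjusted p = 0.274 with an estimated correlation. The photolyase and cryptochrome family was called lower at a camera FDR of 0.0489 (adjusted p = 0.274 with an estimated correlation), with PHR2 as the member that passed. As the labels name the line for PHR2, its fall was in part given by the choice of line. The list had a median of -0.18 and a mean of -0.50 with 5 of 6 below 0, and a shift of the family without PHR2 was not tested. The call ended with RLE size factors (FDR 0.0513) and with organellar genes left out (0.0516). Called higher were the oxidative and singlet oxygen response (median 1.27, 0 of 19 adjusted over the list alone, adjusted p = 0.276 with an estimated correlation), the circadian clock (median 0.46, 0 of 17 adjusted over the list alone, adjusted p = 0.388 with an estimated correlation) and plastid-encoded expression and housekeeping genes (median 0.53, 1 of 18 adjusted over the list alone, adjusted p = 0.551 with an estimated correlation). Per library, the oxidative list overlapped between the genotypes: its median was -0.28, 1.54 and 0.91 in geralt libraries 1, 3 and 7 and -0.35, 0.87 and -0.69 in wild-type libraries 2, 4 and 8. CLPP1 of the plastid-encoded expression list, a Clp protease subunit, had a log2 fold change of 1.35 (SE 0.31, adjusted p = 0.0814). The iron list held IRT1, the root iron transporter, at a log2 fold change of -7.61 (SE 1.60, adjusted p = 0.0688).

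Of the remaining lists, light signalling and greening regulators had a median of 0.00 with GLK1 as the passing member, and cell division and meristem had a median of -0.26 with STM as the passing member. No member passed of chlorophyll breakdown (median -0.50), the heme and bilin branch (-0.53), plastid transcription machinery (-0.15), flavonoid and anthocyanin biosynthesis (-0.45), heat shock and chaperones (0.65), salicylic acid and defence (-0.48), jasmonate (-0.30), seed storage and late embryogenesis (1.13), senescence and starvation (-0.29) or age and phase transition (0.20). Root markers, which stand for another organ within the seedling, had a median of 0.20 and a mean of -0.25, with a camera FDR of 0.794.

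The largest falls outside the lists were AT4G13575 (log2 fold change -9.84, SE 0.71; 4232 reads in wild type and 4 in geralt, a ratio of 915 with a 95% counting interval of 357 to 3359), AT4G19430 (-8.42, SE 1.52; ratio 286, interval 139 to 712), AT3G55240 (-7.95, SE 0.94) and AT1G77960 (-6.36, SE 0.81; ratio 83.1, interval 38.0 to 228). COR413IM1, a cold-regulated protein of the inner plastid envelope, fell by 5.26 (SE 0.80), and SWEET10, a sugar transporter, fell by 4.71 (SE 0.71). AK3, an aspartate kinase, fell by 2.96 (SE 0.32). The largest rises outside the lists were CXE17, a carboxylesterase (2.23, SE 0.37), ATL68 (1.63, SE 0.27), AT1G08910 (1.3, SE 0.23), E13L3 (1.27, SE 0.22) and PUP21, a purine permease (1.25, SE 0.22).

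By edgeR, 55 genes passed at 5 days, 7 higher and 48 lower, and in each of them the 3 geralt libraries lay apart from the 3 wild-type libraries. Of all tested genes 27.2% did so, where chance gives 10%. DESeq2 called 871 genes, 295 higher and 576 lower, and a fit to these 6 libraries alone 960. Camera called 14 of 27 lists, 3 higher and 11 lower, and none held with an estimated correlation (adjusted p = 0.270 to 0.551 with an estimated correlation). Among called lists, medians per library overlapped between the genotypes for plastid-encoded expression, plastid ribosomal proteins, the photolyase family and the oxidative list. The gene count was 4 without geralt library 1, 10 without geralt library 3, 12 without geralt library 7 and 11 without wild-type library 2 or 8. It was 169 without wild-type library 4, 208 without wild-type library 12, 314 without geralt library 5 and 364 without wild-type libraries 4 and 12 together. In wild-type library 4, each of 7 genes under 0.5 CPM in the other 5 wild-type libraries and over 2 CPM in each geralt library stood at 30.8% to 52.1% of the geralt mean at 5 days. These limits were chosen after the data were seen, and the genes were picked by the other 11 libraries. The call of the plastid-encoded expression list ended without wild-type library 2 (FDR 0.158) or geralt library 3 (0.0658) or 7 (0.18). Its median log2 fold change was 0.90 without geralt library 1, 0.81 without wild-type library 4 and 0.34 without geralt library 7. Medians also moved by over 1.5 times for plastid ribosomal proteins without wild-type library 4 (-0.50), the photolyase list without wild-type library 8 (-0.10) and phosphate starvation without geralt library 1 (-0.66). The call of the photolyase list ended without geralt library 3 (0.0658), 5 (0.0670), 7 (0.0970), 9 (0.0573) or 11 (0.0704), or wild-type library 6 (0.0538), 8 (0.125), 10 (0.0670) or 12 (0.0582).

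**Figure D2:**
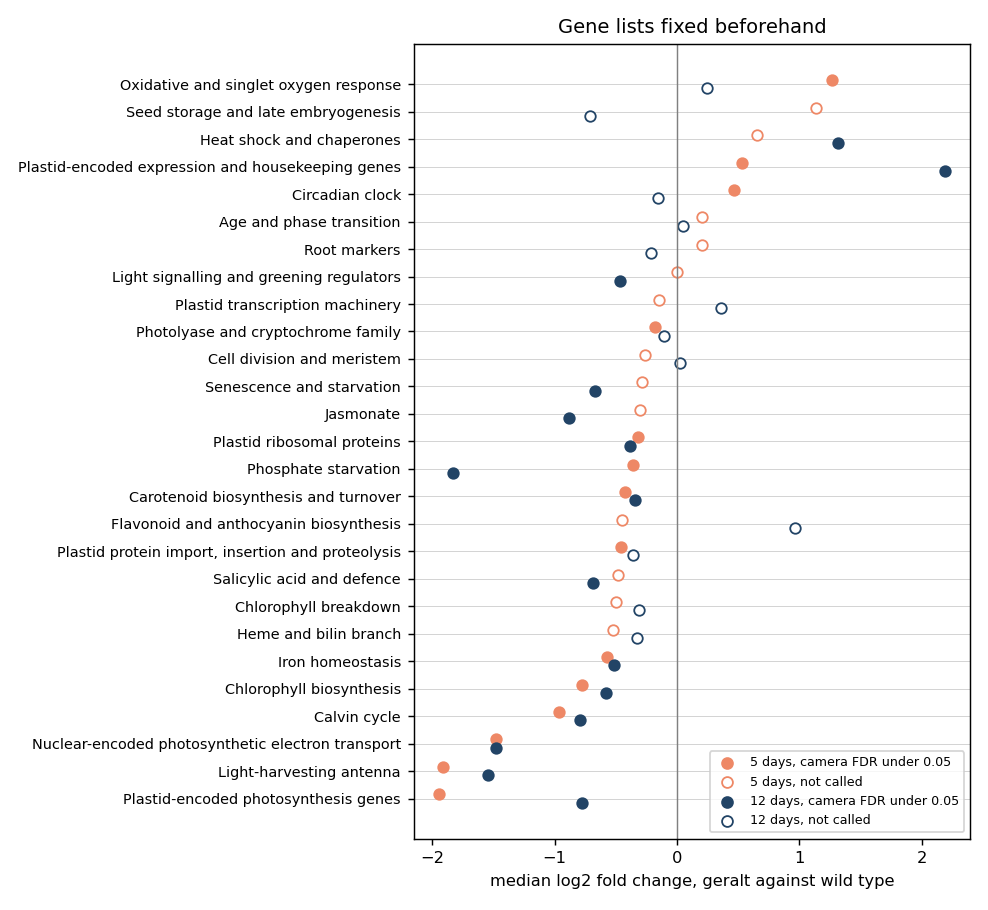
Median log2 fold change of geralt against wild type for each of the 27 gene lists at 5 and at 12 days; filled points passed camera at an FDR under 0.05 with the preset correlation. Light-harvesting antenna genes lie at -1.91 and -1.54, and plastid-encoded expression genes at 0.53 and 2.19.

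At 12 days, the genes past the threshold included GLK1 and SQD2, both lower in geralt, and CLPP1 and STM, both higher. GLK1 fell from 217 ± 55.4 to 33.5 ± 9.76 CPM (SD, n = 3; log2 fold change -2.70, SE 0.42). CLPP1 rose from 13.7 ± 4.49 to 69.7 ± 20.2 CPM (SD, n = 3; log2 fold change 2.35, SE 0.32). SQD2, which makes the sulfolipid that stands in for phospholipid when phosphate is short, fell from 212 ± 121 to 41.0 ± 15.7 CPM (SD, n = 3; log2 fold change -2.37, SE 0.43). STM rose again, from 6.70 ± 0.847 to 18.0 ± 0.684 CPM (SD, n = 3; log2 fold change 1.43, SE 0.25).

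Plastid-encoded expression and housekeeping genes had a median log2 fold change of 2.19 (camera FDR = 2.04e-15, adjusted p = 0.258 with an estimated correlation), with 4 of 18 higher over all genes and 13 adjusted over the list alone. The others that rose were RPOB and RPOC1, subunits of the plastid RNA polymerase (2.18, SE 0.39, and 2.17, SE 0.43), and RPL20, a ribosomal protein (3.24, SE 0.65). Plastid-encoded photosynthesis genes had a median of -0.77 (camera FDR = 0.00989, adjusted p = 0.658 with an estimated correlation), with ATPB, of the plastid ATP synthase, as the only one of 26 to pass (-1.33, SE 0.26) over all genes and 1 adjusted over the list alone. Per library, the median of the expression list minus that of the photosynthesis list ran from 0.60 to 2.03 in the 6 geralt libraries and from -2.16 to -0.15 in the 6 wild-type libraries. Reads of plastid genes made up 0.133% to 0.720% of gene reads in geralt and 0.156% to 0.837% in wild type. Wild-type library 12 stood apart, with an expression list median of -2.20 against -0.62 and -0.89 in wild-type libraries 6 and 10, a photosynthesis list median of -0.91 against 1.28 and 1.27, and the lowest plastid (0.156%) and mitochondrial (0.0140%) shares among the wild-type libraries. Without it the expression list had a median log2 fold change of 1.71 (camera FDR = 1.02e-10). The photosynthesis list had medians of -1.33 in geralt library 5 and 0.72 and 0.46 in 9 and 11.

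**Figure D3:**
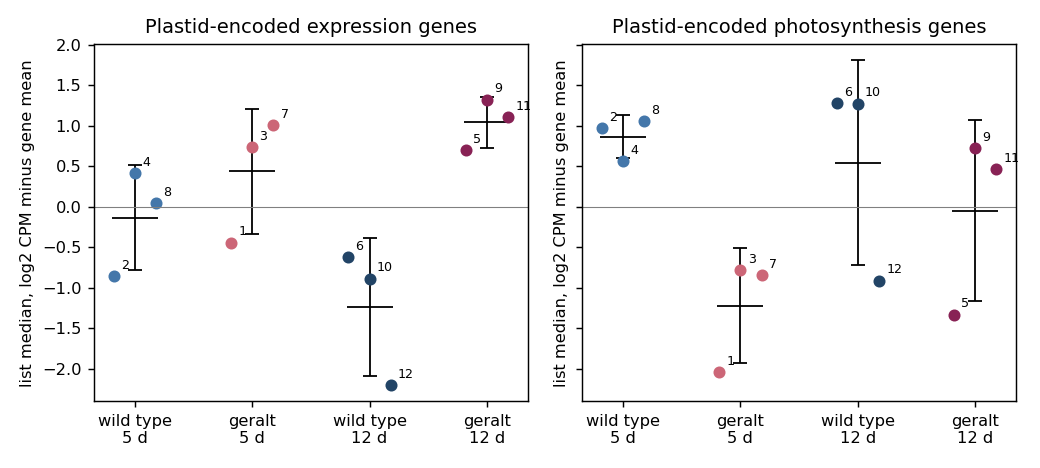
Median over each plastid-encoded list of log2 CPM minus the gene's mean over 12 libraries, per library, by genotype and age in days; points are libraries with their numbers, and bars are the mean and SD of 3 libraries. In the geralt libraries the expression list lies 0.60 to 2.03 above the photosynthesis list, and in the wild-type libraries 0.15 to 2.16 below it.

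Phosphate starvation genes had a median of -1.83 (camera FDR = 3.47e-11, adjusted p = 0.226 with an estimated correlation), with 5 of 17 lower over all genes and 13 adjusted over the list alone. Among them MGD2 and MGD3, galactolipid synthases, fell by 2.45 (SE 0.36) and 3.83 (SE 0.72), and PS2, a pyrophosphatase, fell by 4.6 (SE 0.83). Outside the list, PAP14, a purple acid phosphatase, fell by 7.51 (SE 1.2), and PHT1;2, a phosphate transporter with near-identical neighbours that make its count uncertain, by 7.04 (SE 1.43). Per library, the list median stood at 1.86 in wild-type library 10 and 1.55 in 12, apart from 0.23 in wild-type library 6 and from -0.89, -0.25 and -0.33 in geralt libraries 5, 9 and 11. Without libraries 10 and 12 together, a test chosen after the data were seen, the median log2 fold change was -0.68 with 13 of 17 below 0 (camera FDR = 0.000244, adjusted p = 0.115 with an estimated correlation). Wild type at 12 days then had 1 library, which is assumed to vary like the other groups. Root markers had a median of -0.21 and a camera FDR of 0.415 with all libraries. Per library their median was 0.59, 0.92 and -1.42 in wild-type libraries 6, 10 and 12 and -0.11, 0.60 and -0.28 in geralt libraries 5, 9 and 11. Their median log2 fold change was -0.62 without wild-type library 12, -0.52 without geralt library 9, -0.24 without geralt library 5, -0.083 without wild-type library 6, 0.0065 without geralt library 11 and 0.15 without wild-type library 10.

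Nuclear-encoded electron transport genes had a median of -1.48 (camera FDR = 3.2e-22, adjusted p = 0.258 with an estimated correlation), with 0 of 33 past the threshold of edgeR over all genes and 27 adjusted over the list alone. Antenna genes had a median of -1.54 (camera FDR = 1.26e-12, adjusted p = 0.258 with an estimated correlation), with 0 of 21 over all genes and 15 adjusted over the list alone. Geralt library 5 stood apart in both lists, at -1.78 for electron transport and -1.98 for antenna genes, against -0.11 and -0.11 in library 9 and 0.19 and 0.42 in library 11. Wild type lay at 0.88 to 1.42 and at 0.73 to 1.4. Without library 5 the median log2 fold changes were -1.13 (camera FDR = 2.9e-21) and -1.15 (camera FDR = 4.3e-11). Chlorophyll biosynthesis had a median of -0.58 (camera FDR = 1.41e-08, adjusted p = 0.258 with an estimated correlation), with 1 of 34 lower, PORA (518 reads in wild type and 10 in geralt, a ratio of 43.6 with a 95% counting interval of 23.51 to 91.5), and 13 adjusted over the list alone. The Calvin cycle list was called lower with a median of -0.79 and RBCS2B lower (-4.38, SE 0.86; 1 of 19 adjusted over the list alone), as were carotenoid genes with a median of -0.34 and PSY lower (-1.38, SE 0.27; 4 of 15), each at adjusted p = 0.316 with an estimated correlation. Light signalling and greening regulators (median -0.46, adjusted p = 0.258 with an estimated correlation) were called lower with GLK1 as the passing member. Heat shock and chaperone genes were called higher (median 1.32, camera FDR = 6.75e-06, adjusted p = 0.258 with an estimated correlation), with 7 of 11 adjusted over the list alone. HSP90.1, a cytosolic chaperone, had a log2 fold change of 1.74 (SE 0.42, adjusted p = 0.0733). Called lower without a member past the threshold over all genes were plastid ribosomal proteins (median -0.38, 0 of 22 adjusted over the list alone), jasmonate (-0.88, 4 of 14 adjusted over the list alone), salicylic acid and defence (-0.68, 2 of 15 lower and 1 higher), iron homeostasis (-0.52, 3 of 18) and senescence and starvation (-0.67, 3 of 9). For ribosomal proteins the adjusted p = 0.536 with an estimated correlation, for jasmonate and iron the adjusted p = 0.258 with an estimated correlation, for salicylic acid the adjusted p = 0.437 with an estimated correlation and for senescence the adjusted p = 0.455 with an estimated correlation. The other lists had medians between -0.72 and 0.97 and were not called. The age and phase transition list had a median of 0.05 and a mean of 0.14, against a camera direction of lower.

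Of genes outside the lists, those that rose from few reads were AT1G30170 (log2 fold change 7.64, SE 1.56; 8 reads in wild type and 1474 in geralt, a ratio of 219 with a 95% counting interval of 111 to 508), AT5G53240 (7.03, SE 1.17), AT5G53230 (6.96, SE 1.29), AT4G29200 (6.88, SE 1.39; ratio 125, interval 65.4 to 273), AT5G66150 (4.54, SE 0.91) and AT2G18193 (4.39, SE 0.92). The transcription factor genes NAC044 and NAC103 rose by 4.12 (SE 0.70) and 3.39 (SE 0.63), PDF1.4, a defensin, by 3.81 (SE 0.62), DTX3, an efflux transporter, by 3.32 (SE 0.65), and FLZ8 by 3.16 (SE 0.62). AT4G13575 fell by 8.85 (SE 0.65), AT3G55240 by 6.02 (SE 0.90), FRO5, a metal reductase, by 5.63 (SE 1.09), COR413IM1 by 4.01 (SE 0.74), GRXC13, a glutaredoxin, by 3.82 (SE 0.75) and SWEET10 by 3.32 (SE 0.67).

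On chromosome 4, 3 neighbouring genes, picked after their values were seen, had few reads in geralt: UNE15 (bases 7879558 to 7883926), AT4G13575 (7890249 to 7893761) and AT4G13577 (7895719 to 7898499). UNE15 had 78 reads in wild type and 2 in geralt at 5 days and 201 and 5 at 12 days, with log2 fold changes of -5.11 (SE 1.13, adjusted p = 0.0738) and -5.15 (SE 1.03, adjusted p = 0.0452). AT4G13577 had 79 and 8 reads and then 71 and 1, with log2 fold changes of -3.36 (SE 1.00, adjusted p = 0.162) and -5.53 (SE 1.28, adjusted p = 0.0660). Ratios of reads, with 95% counting intervals, were 33.7 (9.03 to 283) and 33.8 (14.3 to 105) for UNE15 and 8.54 (4.13 to 20.5) and 59.8 (10.4 to 2393) for AT4G13577. The flanking genes AT4G13550 and DIR18 had log2 fold changes of -0.43 and -0.40 at 5 days and -0.16 and -0.34 at 12 days and did not pass.

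**Figure D4:**
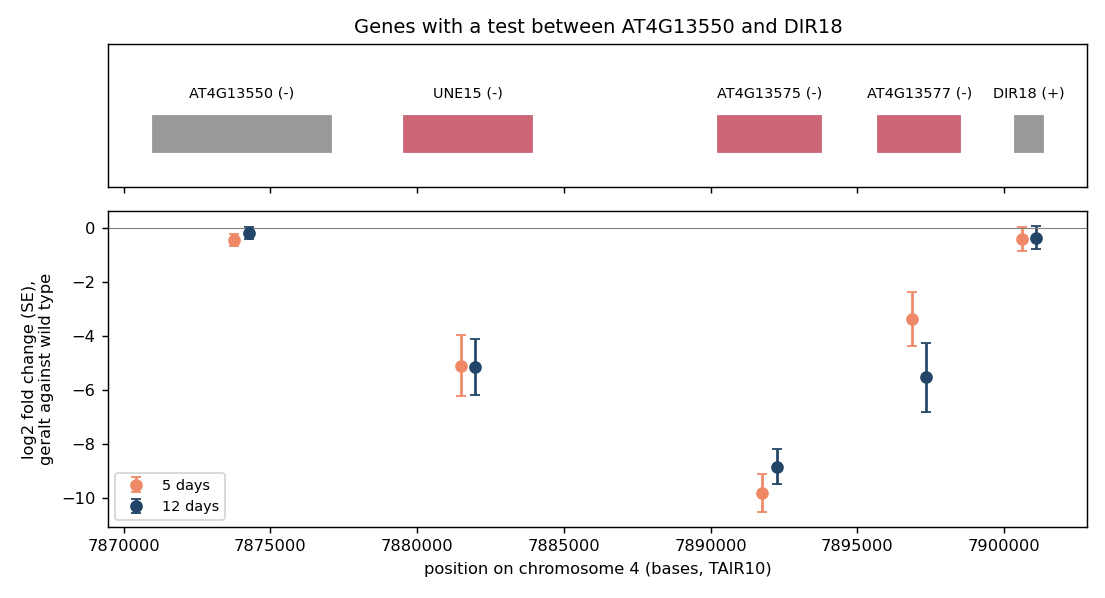
Gene positions on chromosome 4 and log2 fold changes of geralt against wild type with standard errors at 5 and at 12 days, for 3 neighbouring genes and the flanking genes. AT4G13575 lies at -9.84 and -8.85, and the flanking AT4G13550 at -0.43 and -0.16.

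By edgeR, 169 genes passed at 12 days, 92 higher and 77 lower, each without overlap between the genotypes. Of all tested genes 19.1% did so, where chance gives 10%. DESeq2 called 1342, 646 higher and 696 lower, and a fit to these 6 libraries alone 7. Camera called 15 lists, 2 higher and 13 lower, and none held with an estimated correlation (adjusted p = 0.226 to 0.658 with an estimated correlation). Among called lists, medians per library overlapped between the genotypes for plastid-encoded photosynthesis, the Calvin cycle, plastid ribosomal proteins, light signalling, carotenoids, salicylic acid and senescence. The gene count was 4 without geralt library 9, 7 without geralt library 5, 12 without wild-type library 10, 13 without wild-type library 12, and 12, 16 and 13 without geralt libraries 1, 3 and 7. It was 54 and 83 without wild-type libraries 2 and 8, 263 without geralt library 11, 504 without wild-type library 6 and 71 without wild-type libraries 4 and 12 together. The plastid-encoded photosynthesis call ended without geralt library 5 (FDR 0.484) or wild-type library 6 (0.178) or 10 (0.361). Calls also ended for plastid ribosomal proteins without geralt library 5 (0.0825) or wild-type library 6 (0.0675) and for iron homeostasis without wild-type library 6 (0.107). That of salicylic acid and defence ended without geralt library 5 (0.114) or 11 (0.0692) or wild-type library 12 (0.254), and that of senescence and starvation without geralt library 5 (0.132) or wild-type library 10 (0.251) or 12 (0.0616). Without wild-type libraries 4 and 12 together these calls also ended (0.283 and 0.0705). Without geralt library 5 the median log2 fold change was -0.34 for plastid-encoded photosynthesis, -0.44 for the Calvin cycle, -0.23 for plastid ribosomal proteins and -0.85 for iron homeostasis. Without geralt library 11 it was -0.65 for ribosomal proteins, -0.54 for carotenoids and -1.18 for iron, and without geralt library 9 it was -1.07 for senescence. Without wild-type library 6 it was -1.09 for salicylic acid and -0.34 for iron, without wild-type library 10 -0.42 for photosynthesis, -0.83 for iron and -0.40 for senescence, and without wild-type library 12 -0.15 for light signalling and -0.22 for salicylic acid.

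Across the ages, 2 genes were higher and 16 lower at both, and 0 changed in opposite directions, where independent lists would share 0.0305 and 0.175. The 2 higher genes were STM and AT5G13370. Among the 16 lower genes were PHR2, GLK1, PSY, RBCS2B, COR413IM1, SWEET10 and CLA1, the entry enzyme of plastid isoprenoid synthesis. Of the 55 genes called at 5 days 52 had the same sign at 12 days, and of the 169 called at 12 days 158 had the same sign at 5 days, as did 57.0% of all tested genes. The change was smaller at the other age for 50 of the 55 and 152 of the 169. Across all tested genes, which are not independent replicates, the fold changes of both ages had a Pearson correlation of 0.40 and a Spearman correlation of 0.262.

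Whether the genotype difference itself changed with age was tested by the interaction, as the series title calls the gene an age-dependent regulator. No gene passed: edgeR called 0, with 2185 at an unadjusted p under 0.05 and a smallest adjusted p of 0.438, and DESeq2 called 70. At the level of lists, plastid-encoded photosynthesis genes had a less negative difference at 12 than at 5 days (median interaction 1.44, 24 of 26 above 0), and plastid-encoded expression genes a larger positive one (1.32, 18 of 18), each at adjusted p = 0.658 with an estimated correlation. Heat shock and chaperones (0.66) and flavonoid and anthocyanin biosynthesis (1.33) were also shifted upwards, and phosphate starvation (-0.65), the circadian clock (-0.56), light signalling and greening regulators (-0.26) and jasmonate (-0.61) downwards. For the flavonoid list the adjusted p = 0.942 with an estimated correlation, and for the others the adjusted p = 0.658 with an estimated correlation. RBCL had an interaction of 4.90 (SE 1.41) and PS2 one of -4.42 (SE 1.08), each at an adjusted p of 0.438. Camera thus called 8 lists, none with an estimated correlation (adjusted p = 0.658 to 0.942 with an estimated correlation). The list count was 5 without wild-type library 8, and the gene count 2 without wild-type library 6. Circadian clock lost its call without geralt library 5 (FDR 0.0649), and the flavonoid, light signalling and jasmonate calls ended without that library at 0.743, 0.104 and 0.103. The flavonoid call also ended without geralt library 1 (0.0842) or wild-type library 8 (0.0536) or 12 (0.439), with a minimum of 1 CPM in 3 libraries (0.290) and without libraries 4 and 12 together (0.279), which also ended the light signalling (0.181) and jasmonate (0.0806) calls. The light signalling call also ended without geralt library 1 (0.0531), 3 (0.0801) or 11 (0.0522) or wild-type library 2 (0.0712), 4 (0.0723), 8 (0.0590), 10 (0.0794) or 12 (0.169), and the jasmonate call without geralt library 7 (0.137) or 11 (0.0627) or wild-type library 4 (0.118), 8 (0.0593) or 10 (0.2). The median interaction without geralt library 5 was -0.19 for flavonoids, -0.30 for the clock and -0.27 for jasmonate. Without wild-type library 6 it was 2.13 for flavonoids and -1.17 for phosphate, without wild-type library 10 -0.12 for light signalling and -0.37 for jasmonate, and without wild-type library 12 -0.16 for light signalling and 1.12 for heat shock. It was 1.23 for heat shock without geralt library 7 and -0.17 for light signalling without geralt library 9.

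In wild type, from 5 to 12 days, phosphate starvation genes were higher as a group (median 1.32, camera FDR = 6.81e-07, adjusted p = 0.342 with an estimated correlation) and heat shock and chaperone genes lower (median -1.50, camera FDR = 2.57e-07, adjusted p = 0.342 with an estimated correlation). Also called higher were the circadian clock (0.58), jasmonate (0.62), salicylic acid and defence (0.91), senescence and starvation (0.87), age and phase transition (0.31), nuclear-encoded electron transport (0.46) and light signalling (0.36), and lower were plastid-encoded expression genes (-0.80), flavonoid biosynthesis (-1.05) and cell division and meristem (-0.43). For electron transport the adjusted p = 0.746 with an estimated correlation, for jasmonate the adjusted p = 0.588 with an estimated correlation and for the other 8 of these lists the adjusted p = 0.659 with an estimated correlation. The phosphate list median per library was 1.86 and 1.55 in libraries 10 and 12 and 0.23 in library 6 at 12 days, and -0.15 to 0.05 at 5 days. SQD2 had a log2 fold change of 2.12 (SE 0.43) and SOC1, a flowering regulator, one of 1.73 (SE 0.44), each at an adjusted p of 0.142. No gene passed: edgeR called 0, with 4179 at an unadjusted p under 0.05 and a smallest adjusted p of 0.142, and DESeq2 called 1131. Without wild-type library 6 edgeR called 426. None of the 12 called lists held with an estimated correlation (adjusted p = 0.342 to 0.746 with an estimated correlation). Among called lists, medians per library overlapped between the ages for plastid-encoded expression, light signalling, salicylic acid, jasmonate, cell division and senescence. The list count was 7 without wild-type library 4, and 7 without libraries 4 and 12 together. Without library 12, lists past the threshold with all libraries had FDRs of 0.442 for flavonoid biosynthesis, 0.177 for light signalling, 0.326 for salicylic acid, 0.0930 for plastid-encoded expression, 0.0883 for senescence and 0.0537 for cell division. Without library 4 they were 0.241 for electron transport, 0.0818 for light signalling and senescence, 0.0728 for salicylic acid and 0.0545 for cell division. Without library 10 they were 0.188 for senescence and 0.0652 for light signalling and cell division, and without library 2 they were 0.0570 for light signalling and senescence and 0.0593 for flavonoid biosynthesis. The flavonoid call ended too without geralt library 7 (0.0660) or 11 (0.0589), with no low-count filter (0.0520) and with a minimum of 1 CPM in 3 libraries (0.158), which also ended that of age and phase transition (0.0519). Without library 12 the median log2 fold change was 0.15 for light signalling, -0.57 for flavonoids, 0.31 for salicylic acid and 0.57 for age and phase transition, and without library 10 it was -0.25 for cell division and 0.37 for senescence. Without library 6 it was -1.71 for flavonoids, -0.71 for cell division and 1.42 for senescence. For electron transport it was 0.78 without library 2, 0.21 without library 4 and 0.72 without library 8, for age and phase transition 0.49 without library 2 and 0.70 without library 8, and for flavonoids -0.62 without library 2.

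In geralt, from 5 to 12 days, plastid-encoded photosynthesis genes (median 1.28, 25 of 26 above 0, camera FDR = 5.8e-16, adjusted p = 0.708 with an estimated correlation) and antenna genes (median 0.94, 21 of 21, camera FDR = 5.63e-10, adjusted p = 0.708 with an estimated correlation) were called higher. Geralt library 5 at 12 days lay below each 5-day library for antenna, electron transport, Calvin cycle, carotenoid and phosphate genes. For antenna genes it had a list median of -1.98 against -0.83, -1.36 and -1.53 in libraries 1, 3 and 7 at 5 days and -0.11 and 0.42 in libraries 9 and 11. For electron transport it had -1.78 against -0.76, -0.87 and -1.29, for the Calvin cycle -1.25 against -0.42, -0.76 and -0.90, for carotenoids -0.43 against -0.30, -0.38 and -0.35, and for phosphate -0.89 against -0.56, -0.72 and -0.65. For plastid-encoded photosynthesis it lay among the 5-day libraries, at -1.33 against -2.04, -0.78 and -0.85, with 0.72 and 0.46 in libraries 9 and 11. RBCL had a log2 fold change of 4.35 (SE 1.09, adjusted p = 0.801) and LHCB4.3 one of 1.62 (SE 0.38, adjusted p = 0.801). Electron transport (0.58), plastid-encoded expression (0.49), Calvin cycle (0.55), chlorophyll biosynthesis (0.21), chlorophyll breakdown (0.32), carotenoid (0.28), salicylic acid (0.33) and phosphate (0.28) lists were also called higher, and oxidative and singlet oxygen response (-0.43) and heat shock (-0.57) lower. For the oxidative list the adjusted p = 0.640 with an estimated correlation, and for the others the adjusted p = 0.708 with an estimated correlation. No gene passed: edgeR called 0, with 974 at an unadjusted p under 0.05 and a smallest adjusted p of 0.541, and DESeq2 called 62. The 974 are fewer than the share of 0.05 of the 21122 tested genes that chance alone would give. Without geralt library 5 edgeR called 8. None of the 12 called lists held with an estimated correlation (adjusted p = 0.640 to 0.708 with an estimated correlation). Without geralt library 11 the FDR was 0.929 for chlorophyll biosynthesis, 0.944 for the Calvin cycle, 0.930 for carotenoids, 0.451 for electron transport and 0.0649 for chlorophyll breakdown. List medians per library overlapped between the ages for 11 of the 12 called lists, and not for chlorophyll breakdown. The list count was 18 without geralt library 5, 8 without library 9 and 6 without library 7. Without library 7 the FDR was 0.354 for heat shock, 0.0892 for the Calvin cycle, carotenoids and phosphate, 0.0699 for chlorophyll biosynthesis and 0.0529 for chlorophyll breakdown. Without library 9 it was 0.301 for heat shock, 0.268 for salicylic acid, 0.309 for phosphate, 0.156 for the Calvin cycle and 0.0542 for plastid-encoded expression. Without library 1 it was 0.90 for plastid-encoded expression, 0.188 for salicylic acid and 0.0790 for heat shock, and the phosphate call ended without library 3 (0.119) or 5 (0.0590). Without library 11 the median log2 fold change was 0.38 for antenna genes, 0.25 for electron transport, 0.08 for the Calvin cycle and carotenoids, 0.10 for chlorophyll breakdown, -0.04 for chlorophyll biosynthesis and 0.55 for salicylic acid. Without library 5 it was 0.98 for electron transport, 0.84 for the Calvin cycle, 0.45 for phosphate and -1.02 for the oxidative list, and without library 9 it was 0.05 for salicylic acid and 0.07 for phosphate. Without library 1 it was 0.05 for plastid-encoded expression, without library 3 -0.87 for heat shock, and without library 7 0.96 for plastid-encoded expression, -0.21 for heat shock and 0.74 for salicylic acid. The oxidative list, which gained a tested gene in 10 of these 12 fits, was at -1.02 to -0.26.

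Altogether 6 measures of the libraries were compared between genotypes. The 100 most abundant genes took 23.4% ± 3.70 of gene reads in geralt and 34.3% ± 6.25 in wild type (SD, n = 6; two-sided exact permutation p = 0.005, adjusted 0.03), where 0.005 is the smallest p that 400 arrangements allow. Intron reads made up 1.26% ± 0.252 in geralt and 0.945% ± 0.167 in wild type (SD, n = 6; exact permutation p = 0.035, adjusted 0.07), and mitochondrial genes 0.156% ± 0.0602 and 0.0743% ± 0.0340 (SD, n = 6; exact permutation p = 0.03, adjusted 0.07). The share of plastid genes (exact permutation p = 0.145, adjusted 0.18), total reads (0.15, adjusted 0.18) and the share of listed genes in the authors' RPKM scale (0.4, adjusted 0.4) did not pass either. In the last of these wild-type library 12 stood apart, at 97.8% against 63.1% to 80.8% in the other libraries.

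The authors' deposited table for 5 days holds 2223 genes at an FDR-adjusted p under 0.05, 1036 higher and 1187 lower, and that for 12 days 568, 251 higher and 317 lower. All 55 genes called here at 5 days are among those of the authors' deposited table, as are 147 of the 169 called here at 12 days, each with the same sign. In the authors' deposited table PHR2 has a log2 fold change of -2.68 at 5 days and -2.80 at 12 days.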

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

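Of the tests in this part, the splits of the libraries for the interaction were planned, and those on plastid RNA, on single libraries, on wild-type libraries 10 and 12 and on root tissue were chosen after the results were seen. For 8 gene lists camera put the difference between genotypes at 12 days apart from that at 5 days, and this interaction brought them here. Their median interactions were 1.44 for plastid-encoded photosynthesis genes, 1.32 for plastid-encoded expression and housekeeping genes, 1.33 for flavonoid and anthocyanin biosynthesis, 0.66 for heat shock and chaperones, -0.26 for light signalling and greening regulators, -0.56 for the circadian clock, -0.61 for jasmonate and -0.65 for phosphate starvation. With an estimated correlation none passed (adjusted p = 0.658, and 0.942 for the flavonoid list). Of 100 splits drawn from 200 possible ones, 78 gave 8 or more lists and the highest gave 20. Splits that exchange libraries between the genotypes can carry the shared genotype difference into the interaction, so this share does not measure chance. Chance is thus not excluded for these lists. For genes the real count by edgeR was 0, with 2185 at an unadjusted p under 0.05 and 70 by DESeq2. All 100 splits reach 0 by construction, so they say nothing about chance there. The highest other count, 1167, came from the split that exchanges the genotypes at 1 age, which turns the shared genotype difference into an interaction and so shows a structure of the samples.

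The plastid-encoded lists moved apart from each other: the expression list minus the photosynthesis list was higher in each of 6 geralt libraries (0.60 to 2.03) than in each of 6 wild-type libraries (-2.16 to -0.15). More or less plastid RNA carried into a library, if it moved both lists alike, would not set them apart in this way. The difference between them had an exact permutation p of 0.005, the smallest that 400 arrangements can give. That p is no independent support, as the difference was chosen after the shifts were seen in these same libraries. Per library, the expression list at 12 days had medians of 0.70, 1.32 and 1.11 in geralt and -0.62, -0.89 and -2.20 in wild type. The photosynthesis list at 5 days had -2.04, -0.78 and -0.85 in geralt and 0.97, 0.56 and 1.05 in wild type. Their calls held without each library (highest camera FDR 1.02e-10, median 1.71, without wild-type library 12, and 5.39e-13, without geralt library 1). Neither passed with an estimated correlation (adjusted p = 0.258 and 0.270), so camera alone does not decide. Medians that lie apart stay apart when a library is left out, so leaving one out adds no test of them. As each geralt median lay apart from each wild-type median in these 2 cases, a single library with unusual plastid reads is argued against for both. It stays open for the photosynthesis list at 12 days, whose call ended without geralt library 5 (0.484) or wild-type library 6 (0.178) or 10 (0.361) (adjusted p = 0.658 with an estimated correlation), and for the expression list at 5 days, whose call ended without wild-type library 2 (0.158) or geralt library 3 (0.0658) or 7 (0.18) (adjusted p = 0.551 with an estimated correlation). Differences in polyadenylation of plastid transcripts stay open too, as polyadenylated RNA was selected, and no biological explanation was tested.

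Phosphate starvation genes were lower in geralt at 12 days (median log2 fold change -1.83). Less root tissue in the geralt libraries would lower root markers too, and stays open: their median was -0.21 (quartiles -0.91 and 0.12, 14 genes), but -0.62 (quartiles -1.19 and -0.36) without wild-type library 12 and -0.52 without geralt library 9, and wild-type library 12, at -1.42, lay far from libraries 6 and 10 (0.59 and 0.92). That libraries 10 and 12 of wild type (list medians 1.86 and 1.55, against 0.23 in library 6) make the difference stays open in part: without both, camera FDR was 0.000244 and adjusted p = 0.115 with an estimated correlation, and the median was -0.68, so most of its size came with these libraries. With all libraries the list did not pass with an estimated correlation (adjusted p = 0.226 with an estimated correlation). Whether the genotype itself or a difference in growth or harvest between the groups lies behind the shift stays open and was not tested.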

How the results depend on the processing

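Leaving out wild-type libraries 4 and 12 together was chosen after the data were seen, as was camera on the age contrasts. Except where the construction shows it (fewer libraries, a stricter threshold), the cause was not tested.

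The 5-day count of 55 genes became 960 in a fit to the 6 libraries compared, 364 without libraries 4 and 12, 871 by DESeq2 and 11 at an FDR of 0.01. The 12-day count of 169 became 7, 71, 1342 and 1 in the same order. DESeq2 called all 55 and all 169 of these genes. On simulated data with 200 changed genes, 21.7% and 23.1% of its 198 and 195 calls were unchanged genes. Such a share depends on how many genes change, so it does not carry over to the 871 and 1342 calls here. Other filters, size factors, unique reads, a robust spread and a 2-fold minimum gave 54 to 68 and 155 to 217. By edgeR the interaction and the age contrasts gave 0 genes (2185, 4179 and 974 at an unadjusted p under 0.05), against 70, 1131 in wild type and 62 in geralt by DESeq2.

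Leaving out 1 library gave 4 (without geralt library 1) to 314 genes (without geralt library 5) at 5 days and 4 (without geralt library 9) to 504 (without wild-type library 6) at 12 days. It gave 0 to 2 for the interaction and 0 to 426 in wild type (each highest without wild-type library 6), and 0 to 8 in geralt (without geralt library 5). PHR2 stayed lower, at -3.02 to -2.33 at 5 days and -2.85 to -2.69 at 12 days.

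With an estimated correlation 0 lists were called in each of the 5 contrasts. Leaving out 1 library gave 5 (without wild-type library 8) to 10 lists for the interaction, 7 (without wild-type library 4) to 14 in wild type and 6 (without geralt library 7) to 18 (without geralt library 5) in geralt. Without libraries 4 and 12 wild type had 7.

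By the sign of a gene or the direction camera gave a list, 7 results reversed. Without geralt library 11, the camera direction of chlorophyll biosynthesis (FDR 0.929, median -0.04) and the Calvin cycle (0.944, median still above 0 at 0.08) turned from 5 to 12 days in geralt, where their FDRs were as low as 1.48e-05 and 4.88e-14 without library 5. The median of the flavonoid interaction, not counted here, went from 1.33 to -0.19 without geralt library 5. Without that library GSTF12 (-1.39, elsewhere up to 2.51) and DFR (-1.22, up to 3.03) reversed from 5 to 12 days in geralt, as did PCNA1 at 12 days (-0.080, up to 0.83). CDKB2;1 at 12 days was 0.21 without wild-type library 6 and as low as -0.44 without library 10, and RPE in wild type was -0.11 without libraries 4 and 12.

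Depth was not varied. On data simulated at the depth of these libraries edgeR recovered 17.9% of 2-fold and 73.1% of 4-fold changes at 5 days.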

Other observations

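In this part the splits for the genotype comparisons and for genes across ages were planned, and those for lists across ages and for the mean of both ages were chosen after the results were seen. The tests on chromosome 4, library 4, glucosinolates and mitochondrial dysfunction were also chosen after the results were seen.

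Splits of 3 against 3 libraries number 10, too few for a share under 0.05. At 5 days the real split gave 55 genes and 14 lists and the highest other 37 and 13, so that 1 split, the real one, reached each. At 12 days it gave 169 genes and 15 lists against 2 and 17, with 1 split and 3 splits as large. From 5 to 12 days edgeR gave 0 genes in all 10 splits of either genotype, the real ones included, which says nothing about chance. The real ones had 4179 genes in wild type and 974 in geralt at an unadjusted p under 0.05, and DESeq2 gave 1131 and 62. Chance alone would put a share of 0.05 of the 21122 tested genes there, and the geralt count lies below that share. For lists the real splits gave 12 and 12 against a highest other of 15 and 18, with 3 and 6 splits as large.

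Averaged over both ages, a contrast added after the data were seen, 1167 genes passed, 466 higher and 701 lower, and 2231 by DESeq2. Of 100 splits that exchanged genotypes within ages, out of 200, only the real one gave as many, with 13 in the highest other. This argues against chance for this count. It does not exclude chance, as 1 in 100 is the smallest share that this draw can give. Without wild-type library 8 the count was 366, without wild-type library 2 it was 399, without geralt libraries 1, 3 and 7 it was 488, 493 and 485, and without geralt library 9 it was 574.

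The neighbouring genes UNE15, AT4G13575 and AT4G13577 on chromosome 4 were nearly without reads in geralt, and the 2 genes between them had 0 reads in the 12 libraries. At most 8.97% of the wild-type level was left in geralt over the 3 genes and both ages, and 1 of 10000 shuffles of the gene order had so long a run among 38 genes lower by over 8-fold at both ages. The shuffles take neighbouring genes as independent. Genes with adjoining locus codes can change together, as AT3G55240 and AT3G55250 did, both lower at both ages. The share of shuffles may thus overstate how unusual the run is. A candidate explanation is a deleted, rearranged or silenced stretch in the geralt line, apart from PHR2 on chromosome 2. Counts per gene cannot tell these apart, and whether any other difference between the genotypes comes from this stretch was not tested.

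Wild-type library 4 lay between its group and the geralt libraries. Summed over the 3 genes on chromosome 4 it had 15.0 CPM, 84.2 times the highest geralt library (0.179 CPM), which argues against a mislabelled geralt library. Geralt RNA or seedlings mixed into this library may be the explanation. The 7 genes under 0.5 CPM in the other 5 wild-type libraries and over 2 CPM in each geralt library stood in library 4 at 30.8% to 52.1% of the geralt mean at 5 days (median 42.2%), with 260 to 976 reads. A like pick for each other wild-type library left library 4 aside and gave 7 or 8 genes. Medians there were 0.496% to 1.32%, with a highest single gene of 19.0% in library 6. Those picks hold the 7 genes above, which had to be under 0.5 CPM in that library. Their low shares were thus fixed by the choice, and they are no control for library 4. Other limits for library 4 gave 3 or 4 genes and medians of 38.8% to 42.1%.

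Other genes also put a number on the wild-type share in library 4, and the estimates do not match each other. The run on chromosome 4 was at 46.9% of the mean of the other 5 wild-type libraries, 88.8% of the lowest and 35.8% of the highest of them. Antenna genes put the wild-type share at a median of 29.1% (10th to 90th percentile 11.5% to 60.6%, 21 genes) and PHR2 at 28.5%. By the median of the antenna genes and by PHR2, both set against libraries 2 and 8, wild-type RNA was the smaller part of library 4. By the run it was the smaller part against the mean or the highest, and the larger part against the lowest, library 2. The run was set against wild-type libraries of both ages. At 5 days it had 16.9 CPM in library 2 and 33.9 CPM in library 8, against 15.0 CPM in library 4. The 7 genes, at a median of 42.2% of the geralt level, made geralt RNA the smaller part. A simple mixture would give 1 share, and why the estimates differ was not tested. The limits and the test were chosen after the values were seen, and a rise of these 7 genes in unmixed wild-type plants of that library was not tested. Results with library 4 in the wild-type group at 5 days carry this doubt, and the gene count without it was 169 in place of 55.

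A list of 20 aliphatic glucosinolate synthesis genes, written after some had been seen among the genes lower in geralt, had a median log2 fold change of -1.30 at 5 days, with 20 of 20 below 0 and 3 passing: BCAT4, IPMDH1 and CYP79F2. Its camera p with an estimated correlation was 0.00807, and 0.0205 without those 3. At 12 days the median was -0.30 and the p was 0.545, so that a lower level at both ages was not shown.

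A list of 19 genes induced by mitochondrial dysfunction, written after some had been seen among the genes higher in geralt, had a median of 1.94 at 12 days, with 16 of 19 above 0. Those passing were NAC013, UPOX, UGT74E2, CRF6, DTX1 and DTX3. Its camera p with an estimated correlation was 0.0152, and 0.0321 without those 6. At 5 days the median was 0.94 and the p was 0.136, and without those 6 it was 0.358, so that a higher level at both ages was not shown. These camera p, too, are unadjusted and come from a list written from the same data, so they are no independent support.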
